A study of Homo sapiens with 24 samples.

How the data were processed

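BT549, a human triple negative breast cancer cell line, was treated in 3 experiments, and RNA was sequenced from 24 libraries in 8 groups of 3. Per the labels, RNA was depleted of ribosomal RNA, libraries were made with NEBNext kits, and paired end reads were taken on an Illumina NovaSeq sequencer. The submitters' processing notes name bcl2fastq, SAMtools, featureCounts and DESeq2 and the genome build GRCh38. The aligner, the gene annotation and the versions of these tools were not given in the sources used here. The deposited signal of each library was a table of normalized read counts per gene, which the submitters' processing notes credit to DESeq2. Every value divided by a per-library factor gave whole reads within a tolerance of 0.0001, so the reads behind each value could be recovered.

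The knockdown table held 15686 features, of which 21 repeated a symbol, which left 15665 genes. The inhibitor table held 24290 features. Of these, 6462 had no gene symbol and 32 repeated a symbol, which left 17796 genes. Values of features with the same symbol were summed. The unnamed features took no part in the tests and held 1.62% to 26.04% of the recovered reads. The MB-3 table held 10048 genes, the lowest with a mean of 83.9, so genes of low level were missing from that comparison. The recovered depth was 18.77 to 24.15 M reads in the knockdown, 5.582 to 30.76 M in the inhibitor experiment and 8.306 to 19.96 M in the MB-3 experiment. The 3 tables were normalized separately, and each comparison stayed within its own table. Strandedness of the libraries was not given, so a gene that overlaps another on the opposite strand can share its reads. Histone, metallothionein, ribosomal protein and HSPA1 genes have near identical copies or pseudogenes, so their levels are less certain than those of other genes.

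Groups, comparisons, tests, 26 gene lists and the rule for named genes were chosen before the data were examined. Genes with a mean of at least 10 over the fitted libraries were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. This left 14788 genes in the knockdown, 13616 in the inhibitor experiment and 10048 in the MB-3 experiment. The 12 libraries of the inhibitor experiment shared 1 fit, which gave KJ-PYR-9 against VEH, DEX against VEH, KJ-PYR-9+DEX against DEX and the interaction, which is the second KJ-PYR-9 effect minus the first. For MB3 the plan had assumed raw counts and edgeR. Because its files held normalized values, limma was used, as the plan provided for that case. Fold changes are on the log2 scale with the standard error (SE), and levels are means of normalized read counts with the standard deviation (SD, n = 3). Coordinates are on GRCh38. Of 18154 symbols, 17823 matched a RefSeq gene and 17091 a GENCODE transcript.

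The named genes were MYC and KAT2A, the 7 protein-coding genes with the largest rise and the 7 with the largest fall among called genes with a mean of at least 50 and no overlap between the groups, and 3 called members of each of the 5 lists with the smallest p. The other comparisons of the inhibitor experiment took 5 in each direction and 3 lists, with MYC. The results of some of these genes are not reported here. Members of lists that are given as examples beyond this rule were chosen after their values were seen.

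Lists with at least 5 tested members were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the lists within each comparison, and again with an estimated correlation. The lists were the MYC network, ribosome biogenesis, cytosolic ribosomal proteins, MYC-dependent metabolism and growth, E2F and DNA replication, mitosis, replication-dependent histones, SAGA and ATAC complexes, NF-kB and inflammatory cytokines, the NRF2 antioxidant response, YAP and TEAD targets, aryl hydrocarbon receptor targets, basal breast, epithelial and luminal breast, mesenchymal and extracellular matrix, cholesterol synthesis, glucocorticoid-responsive genes, the heat shock response, hypoxia and glycolysis, immediate early genes, the integrated stress and unfolded protein response, leukocyte markers, metallothioneins and metal response, mitochondrially encoded genes, p53 targets and the type I interferon response. Lists shared some genes. The glucocorticoid-responsive list shared DUSP1 and SGK1 with the immediate early genes, MT2A and MT1X with the metallothioneins, and NFKBIA and TNFAIP3 with the NF-kB list. No mitochondrially encoded gene was in the 3 tables, so that list could not be tested. Leukocyte markers were tested in the knockdown alone, and histones were not tested in the MB-3 experiment, for lack of 5 tested members.

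Replicate numbers were checked for pairing by the correlation of residuals between libraries that share a number, with pairing taken where every pair exceeded 0.1. The 3 pairs of the knockdown gave -0.346 to -0.02 and did not pair. The 18 pairs of the inhibitor experiment gave 0.13 to 0.524, and the 3 pairs of the MB-3 experiment gave 0.208 to 0.389. Blocked counts of genes are given for these 2 experiments, and blocked values of named genes and lists where they changed a call. Fold changes of 2 comparisons were correlated across genes, with an exact two-sided permutation test over the 10 by 10 splits of the libraries, whose smallest p is 0.01.

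Alternatives were other pseudocounts, no filter, a mean of at least 50, TMM and quantile scaling, trended and robust variance, a replicate block, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the limma fry test, and each library left out in turn. After the data were seen, the removal of GC content and transcript length trends within each library was added, since such trends ran along with the fold changes. Genes with a GC value made up 97.14% of the tested genes in the knockdown, 97.52% in the inhibitor experiment and 99.19% in the MB-3 experiment. A fit without the 2 libraries with the most reads in unnamed features and the edgeR, pseudocount, scaling and trended variance alternatives for MB3 were also added then. So were leaving out each library in turn from the correlations and the lists, and thinning every library of the inhibitor experiment to the reads of the shallowest.

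The fits were tested on simulated data in which 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. In that order limma recovered 2.99%, 61.2% and 98.5% in the knockdown design, 1.49%, 61.2% and 98.5% for KJ-PYR-9, and 98.5%, 100% and 100% for MB3. It recovered 5.97%, 67.2% and 98.5% for DEX, 7.46%, 67.2% and 100% for KJ-PYR-9+DEX, and 1.49%, 13.4% and 89.4% for the interaction. Unchanged genes that limma also called numbered 10 in the knockdown design, 1 for KJ-PYR-9, 10 for MB3, 4 for DEX, 16 for KJ-PYR-9+DEX and 2 for the interaction. Every simulated gene of a design had the same dispersion, so the recovered shares do not hold for genes with more spread. In the real MB3 fit, GCLM and DDIT3 changed more than 1.5-fold and were not called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.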

Results

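Transcript levels were measured by RNA sequencing in BT549 triple negative breast cancer cells, in 8 groups of 3 libraries. In the knockdown experiment cells received a pool of siRNAs against MYC for 72 h (siMYC) or a control labelled siCtl, whose time is not given. In the inhibitor experiment they received vehicle (VEH), a treatment labelled DEX whose dose is not given, KJ-PYR-9, a small molecule inhibitor of MYC, at 40 µM for 3 h, or both (KJ-PYR-9+DEX). In the MB-3 experiment they received a further vehicle (VEH2) or 100 µM MB-3 for 3 h, an inhibitor of the histone acetyltransferase GCN5 (gene KAT2A). The title of library MB3 1 reads MED3 while its treatment field reads MB3, and it was taken as MB3. The recovered depth of replicates 1, 2 and 3 was 20.5, 18.77 and 24.15 M reads in siCtl and 21.6, 24.03 and 22.74 M in siMYC. It was 30.26, 30.76 and 7.846 M in VEH, 5.582, 14.53 and 12.12 M in DEX, 24.97, 26.92 and 21.17 M in KJ-PYR-9, and 6.886, 12.07 and 8.593 M in KJ-PYR-9+DEX. In VEH2 it was 8.306, 14.18 and 19.96 M, and in MB3 12.56, 14.29 and 10.89 M. Features without a gene symbol took 26.04% of the reads in DEX 1 and 8.722% in KJ-PYR-9+DEX 3, against 1.618% to 1.861% in VEH.

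The first comparison asked which genes changed after knockdown of MYC. The siRNA target MYC, a transcription factor of cell growth (GRCh38 chromosome 8, 127735434 to 127742951), read 1655, 1789 and 1710 in the 3 siMYC libraries and 2313, 2269 and 2138 in the 3 siCtl libraries. All siMYC values lay below all siCtl values, with means of 1718 (SD 67.2) and 2240 (SD 91.2). The log2 fold change of -0.38 (SE 0.11) had a limma adjusted p of 0.0587, which missed the threshold, while edgeR gave an adjusted p of 0.0175 and DESeq2 0.00119. It passed with TMM rescaling (limma adjusted p = 0.0333), with trended and robust variance (0.0321), among genes with a mean of at least 50 (0.0413) and after removal of GC content and length trends (-0.66, 0.0113). KAT2A (chromosome 17, 42113111 to 42121367) averaged 508 (SD 66.1) in siMYC and 599 (SD 36.3) in siCtl (-0.24, SE 0.14, limma adjusted p = 0.242), and after removal of those trends -0.59 with an adjusted p of 0.0253.

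Interferon-induced genes made up the largest rises. The expression of OAS1, an antiviral synthetase that activates RNase L (chromosome 12, 112906962 to 112933219), was 4647 (SD 2073) in siMYC and 95.0 (SD 53.5) in siCtl, a rise of 5.71 on the log2 scale (SE 0.59, limma adjusted p = 0.00665). Its relative OAS2 rose from 384 (SD 239) to 14950 (SD 5208), by 5.47 (SE 0.56, 0.00664), and MX1, a GTPase against RNA viruses (chromosome 21, 41420558 to 41459214), from 1123 (SD 765) to 38510 (SD 10773), by 5.41 (SE 0.65, 0.00946). TRIM22, an antiviral ubiquitin ligase, rose from 5.26 (SD 2.67) to 505 (SD 435), by 5.99 (SE 0.76, 0.0101). RTP4, an interferon-induced inhibitor of viral replication, rose from 2.11 (SD 2.18) to 158 (SD 104), by 5.77 (SE 0.70, 0.00953). IFI27, an interferon-induced mitochondrial protein, rose from 33.0 (SD 14.8) to 1999 (SD 1721), by 5.59 (SE 0.69, 0.00981). ETV7, an ETS family repressor, rose from 4.16 (SD 3.61) to 191 (SD 118), by 5.46 (SE 0.87, 0.0148), and its adjusted p was 0.0538 without siMYC 3. All 26 tested members of the type I interferon response list rose, also when adjusted over the list alone, with a median of 3.97 (limma camera adjusted p = 4.01e-18, adjusted p = 0.378 with an estimated correlation).

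Genes of protein synthesis were down-regulated together. Of 46 cytosolic ribosomal protein genes, 27 fell and none rose (43 fell when adjusted over the list alone), with a median of -0.57 (limma camera adjusted p = 4.01e-18, adjusted p = 0.383 with an estimated correlation). RPL3, a core protein of the large subunit (chromosome 22, 39312882 to 39319623), averaged 9007 (SD 1449) in siMYC and 15849 (SD 223) in siCtl (-0.83, SE 0.15, limma adjusted p = 0.0195). The small subunit genes RPS3A (-0.93, SE 0.17, 0.0197) and RPS23 (-0.83, SE 0.16, 0.0232) fell alike. Of 33 ribosome biogenesis genes, 11 fell and 22 did not pass (19 fell when adjusted over the list alone), with a median of -0.50 (limma camera adjusted p = 1.77e-10, adjusted p = 0.378 with an estimated correlation). Among them were WDR12, which acts in large subunit assembly (333, SD 56.2, against 669, SD 64.1, a change of -1.01, SE 0.16, limma adjusted p = 0.0149), the RNA helicase DDX21 (-0.87, SE 0.19, 0.0317) and WDR43 (-0.77, SE 0.15, 0.0224). After removal of GC content and length trends the limma adjusted p of WDR12 was 0.0595. It was 0.0541 without siCtl 1 and 0.0603 without siCtl 3, and that of DDX21 was 0.0547 without siMYC 2. Without siCtl 1, siCtl 2, siCtl 3 or siMYC 3 the limma adjusted p of RPL3, RPS3A, RPS23, DDX21 and WDR43 was 0.0511 to 0.108.

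Cholesterol synthesis genes fell too, 11 of 25 (16 adjusted over the list alone), with a median of -0.64 (limma camera adjusted p = 7.42e-08, adjusted p = 0.378 with an estimated correlation). The synthase HMGCS1, an early enzyme of the pathway, fell by 1.23 (SE 0.28, limma adjusted p = 0.0338), from 5948 (SD 1184) to 2625 (SD 1008). Among replication-dependent histones H3C2 (-1.09, SE 0.26, 0.036) and H4C3 (-0.91, SE 0.23, 0.0411) fell, 2 of 29 genes (0 adjusted over the list alone), with a list median of -0.58 (limma camera adjusted p = 4.25e-07, adjusted p = 0.462 with an estimated correlation). With any of siCtl 1, siCtl 2, siCtl 3 and siMYC 3 left out the limma adjusted p of HMGCS1, H3C2 and H4C3 was 0.0619 to 0.129, and without siMYC 2 that of HMGCS1 was 0.078. The median of the histone list was -0.32 without siMYC 3.

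The largest falls of single genes lay outside these groups. ADAT2, a subunit of the tRNA adenosine deaminase, fell from 258 (SD 6.83) to 70.1 (SD 14.3), by 1.88 (SE 0.17, limma adjusted p = 0.00551). POLR3G, a subunit of RNA polymerase III, fell from 352 (SD 65.6) to 99.1 (SD 37.8), by 1.87 (SE 0.28, 0.014). The syntaxin binding proteins STXBP5L and STXBP4 fell, with changes of -2.05 (SE 0.45, 0.031) and -1.93 (SE 0.34, 0.0192). FILIP1L and the zinc finger gene ZNF37A fell, with changes of -2.04 (SE 0.49, 0.0371) and -1.80 (SE 0.43, 0.0376). Without siCtl 1, siCtl 2, siCtl 3 or siMYC 3 the limma adjusted p of these 4 genes was 0.0519 to 0.116, and without siMYC 2 it was 0.075 for STXBP5L and 0.0606 for ZNF37A. That of POLR3G was 0.0535 without siCtl 3. HMOX1, the heme-degrading oxygenase (chromosome 22, 35381096 to 35394207), rose from 3789 (SD 376) to 6558 (SD 130), by 0.80 (SE 0.12, limma adjusted p = 0.014, 0.0595 without siCtl 1 and 0.0581 without siCtl 3).

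Further lists were lower in siMYC. Of 30 mitosis genes 5 fell (7 adjusted over the list alone), including the spindle gene ASPM (-1.69), the kinesins CENPE (-1.45) and KIF11 (-1.30) and the proliferation marker MKI67 (-1.06), with a list median of -0.43 (limma camera adjusted p = 4.93e-07, adjusted p = 0.462 with an estimated correlation). Of 28 genes of MYC-dependent metabolism and growth 6 fell (9 adjusted over the list alone), among them the transferrin receptor TFRC (-1.09), the chaperonin HSPD1 (-0.97) and the purine enzymes PPAT (-0.73) and PAICS (-0.66), with a median of -0.37 (limma camera adjusted p = 0.000213, adjusted p = 0.378 with an estimated correlation). The E2F and DNA replication list was called lower with a median of -0.11 (limma camera adjusted p = 0.0382, adjusted p = 0.673 with an estimated correlation), although none of its 30 genes passed, either over all genes or adjusted over the list alone. It missed the threshold with quantile scaling (limma camera adjusted p = 0.0537), without siCtl 3 (0.209), without siMYC 1 (0.101) and without siMYC 3 (0.508), where its median was 0.02. That median was -0.28 after removal of GC content and length trends. The mitosis median was -0.26 without siMYC 3.

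Inflammatory, epithelial, mesenchymal and stress genes were higher. Of 21 NF-kB and cytokine genes 9 rose (13 adjusted over the list alone), among them the chemokine CXCL10 (3.28), the cytokine IL6 (1.65), IRF1 (1.46) and TNFAIP3 (1.41), with a median of 1.02 (limma camera adjusted p = 4.31e-05, adjusted p = 0.462 with an estimated correlation). The epithelial and luminal list had 7 of 16 genes higher (10 adjusted over the list alone), including the cadherin CDH1 (2.04) and the keratins KRT8 (1.67) and KRT18 (1.56), with a median of 0.69 (0.000565, adjusted p = 0.378 with an estimated correlation). In the mesenchymal and matrix list 7 of 29 genes rose and 1 fell (8 and 1 adjusted over the list alone), among them the collagen COL6A3 (2.10), TAGLN (2.06) and fibronectin FN1 (1.18), with a median of 0.52 (0.00609, adjusted p = 0.493 with an estimated correlation). Of 9 metallothionein genes 5 rose (7 adjusted over the list alone), with MT2A at 14068 (SD 1327) against 5197 (SD 376), and a median of 1.01 (limma camera adjusted p = 0.00151, adjusted p = 0.378 with an estimated correlation). Glucocorticoid-responsive genes rose in 9 of 24 cases (10 adjusted over the list alone), led by IGFBP1 (1.89) and CAVIN2 (1.35), with a median of 0.53 (0.00283, adjusted p = 0.378 with an estimated correlation). That median was 0.27 after removal of GC content and length trends. Without siMYC 3 the medians were 0.33 for glucocorticoid-responsive genes and 0.33 for mesenchymal genes, and without siCtl 3 the latter was 0.33.

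Immediate early genes rose in 8 of 30 cases (11 adjusted over the list alone), with the phosphatase DUSP6 at 1.51 and a median of 0.46 (limma camera adjusted p = 0.000581, adjusted p = 0.462 with an estimated correlation). YAP and TEAD targets rose in 6 of 17 cases (10 higher and 1 lower adjusted over the list alone), with GADD45A at 0.99 and a median of 0.50 (0.000581, adjusted p = 0.378 with an estimated correlation). The integrated stress and unfolded protein response had 7 of 28 genes higher (7 adjusted over the list alone), including the transcription factors ATF5 (1.12) and ATF3 (0.91), with a median of 0.35 (0.0157, adjusted p = 0.615 with an estimated correlation). Hypoxia and glycolysis genes rose in 5 of 29 cases (6 adjusted over the list alone), with adrenomedullin ADM at 2.01 and a median of 0.19 (0.0299, adjusted p = 0.615 with an estimated correlation). NRF2 targets rose in 6 of 25 cases (7 adjusted over the list alone), with the reductases AKR1B10 at 2.13 and NQO1 at 0.95 and a median of 0.15 (0.0446, adjusted p = 0.383 with an estimated correlation). The limma camera adjusted p of the stress, hypoxia and NRF2 lists was 0.0741, 0.186 and 0.106 after removal of GC content and length trends, and that of NRF2 was 0.0577 with quantile scaling. The medians after this removal were 0.16, 0.12 and 0.07, and that of the immediate early genes was 0.25. Without siCtl 3 the limma camera adjusted p was 0.144 for the stress and 0.112 for the hypoxia list, without siMYC 3 it was 0.0955 and 0.176, and that of NRF2 was 0.101 without siCtl 1 and 0.0777 without siMYC 2. The median of the hypoxia list was 0.33 without siCtl 1, 0.31 without siCtl 2 and 0.36 without siMYC 2, that of the stress list 0.55 without siMYC 2, and that of NRF2 targets 0.29 without siMYC 1.

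For the remaining lists limma camera gave no call. The adjusted p was 0.0826 for aryl hydrocarbon receptor targets (2 of 6 genes higher), 0.116 for basal breast genes (3 of 13 higher), 0.278 for leukocyte markers (1 of 7 higher), 0.423 for heat shock genes (1 of 17 lower) and 0.54 for the MYC network (1 of 11 higher). It was 0.579 for the SAGA and ATAC complexes (1 of 26 higher), with a median of 0.001 but a mean of -0.01 and a test on the lower side. It was 0.828 for p53 targets (2 of 24 higher and 2 lower), with a median of -0.004, a mean of 0.14 and a test on the lower side. The leukocyte marker with the highest level, CORO1A, averaged 186 (SD 14.8) in siMYC and 231 (SD 10.2) in siCtl.

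In all, limma called 2386 of 14788 genes, including 1679 upregulated and 707 downregulated genes, and 911 of them changed at least 2-fold. TMM rescaling gave 1374 higher and 944 lower genes, quantile scaling 1369 and 1090, edgeR 1703 and 1219, and DESeq2 2020 and 1762. After removal of GC content and length trends 1312 genes were higher and 1498 lower. The count was 570 without siCtl 1, 530 without siCtl 2, 432 without siCtl 3, 3983 without siMYC 1 and 520 without siMYC 3. With each library left out in turn, TRIM22, RTP4, OAS1, OAS2, IFI27, MX1 and ADAT2 kept their calls.

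**Figure D1:**
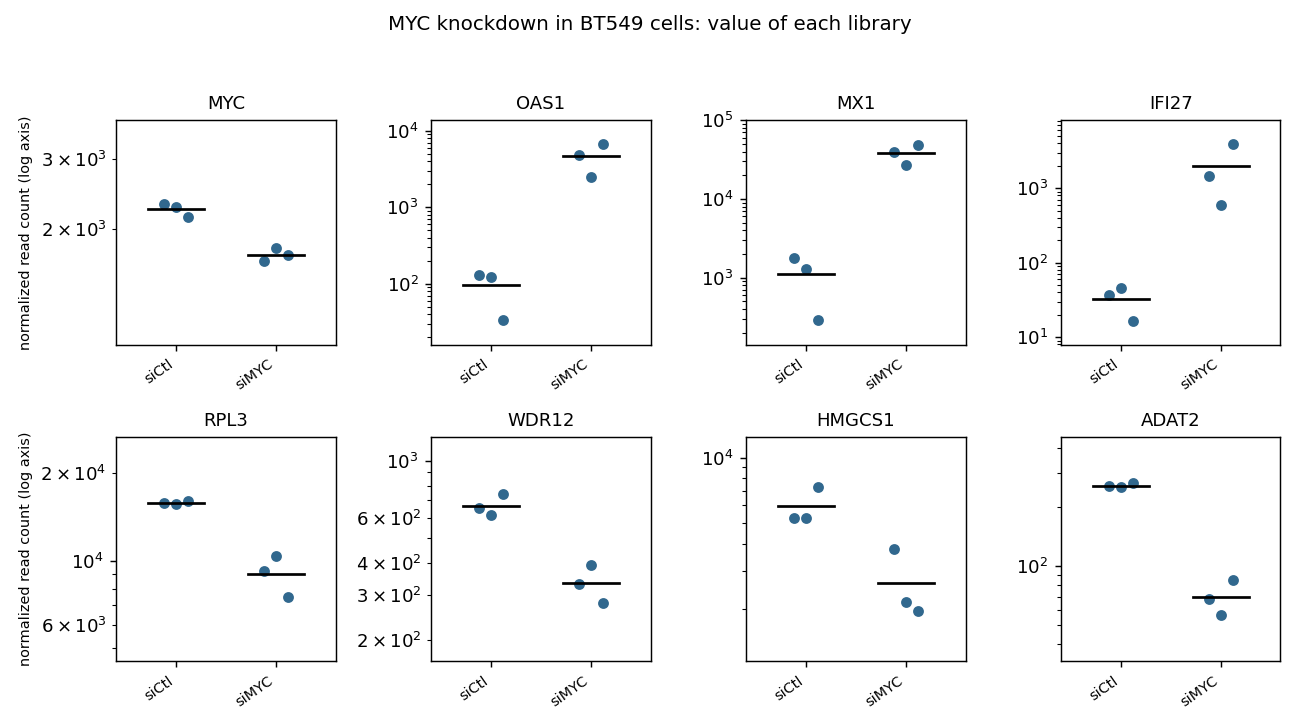
Normalized read counts (log axis) of MYC, OAS1, MX1, IFI27, RPL3, WDR12, HMGCS1 and ADAT2 in siCtl and siMYC, with 1 point per library and a bar at the mean of 3. OAS1 went from a mean of 95.0 to 4647 and ADAT2 from 258 to 70.1, while MYC went from 2240 to 1718.

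The second comparison asked which genes changed within 3 h of KJ-PYR-9. The expression of MYC itself was significantly up-regulated in KJ-PYR-9 compared with VEH, at 9853 (SD 1408) against 1806 (SD 598), a rise of 2.49 (SE 0.21, limma adjusted p = 6.38e-05). FOS, a subunit of the transcription factor AP-1 (chromosome 14, 75278828 to 75282230), rose from 108 (SD 44.2) to 17528 (SD 3947), by 7.40 (SE 0.30, 4e-07). The nuclear receptors NR4A1 and NR4A2 rose by 6.28 (SE 0.31, 1.81e-06) and 5.78 (SE 0.39, 1.48e-05), NR4A1 from 125 (SD 49.8) to 9439 (SD 1481) and NR4A2 from 54.8 (SD 22.7) to 2868 (SD 150). EGR1, a zinc finger factor of the growth factor response (chromosome 5, 138465479 to 138469303), rose from 653 (SD 322) to 26384 (SD 4735), by 5.44 (SE 0.34, 1.05e-05). FOSB, NR4A3 and EGR2 rose by 4.80 (SE 0.25), 4.72 (SE 0.33) and 4.47 (SE 0.38). Of 30 immediate early genes 29 rose and none fell, with 29 also when adjusted over the list alone, and the median was 2.60 (limma camera adjusted p = 8.3e-21, adjusted p = 0.18 with an estimated correlation).

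Histone genes were up-regulated in 22 of 29 cases (23 adjusted over the list alone), with a median of 1.03 (limma camera adjusted p = 2.26e-07, adjusted p = 0.355 with an estimated correlation) that was 0.45 after removal of GC content and length trends. H3C10 rose from 2624 (SD 488) to 8762 (SD 773), by 1.75 (SE 0.19), and H2BC8 and H2BC4 rose by 1.72 (SE 0.17) and 1.69 (SE 0.13). Glucocorticoid-responsive genes rose in 15 of 26 cases (15 higher and 1 lower adjusted over the list alone), with a median of 0.84 (limma camera adjusted p = 2.37e-05, adjusted p = 0.355 with an estimated correlation) that was 0.54 after this removal. Among them were the phosphatase DUSP1, from 388 (SD 153) to 5207 (SD 552), by 3.81 (SE 0.26), the kinase SGK1, by 2.69 (SE 0.23), and PDK4, the kinase that restrains pyruvate dehydrogenase, by 2.35 (SE 0.37). DUSP1 and SGK1 also belong to the immediate early list, so this list is not independent of that one. Mesenchymal and matrix genes rose in 17 of 30 cases (20 adjusted over the list alone), with a median of 0.51 (limma camera adjusted p = 2.37e-05, adjusted p = 0.355 with an estimated correlation, 0.146 with quantile scaling). Examples were the repressor SNAI1 (1.83, SE 0.33) and the collagen COL6A2 (1.48, SE 0.23). Of 46 ribosomal protein genes 29 rose and 1 fell, also when adjusted over the list alone, with a median of 0.52 (limma camera adjusted p = 2.37e-05, adjusted p = 0.376 with an estimated correlation, 0.836 with quantile scaling) that was 0.32 after removal of the trends. RPLP1 rose from 5870 (SD 952) to 16095 (SD 910), by 1.47 (SE 0.23), and RPLP2 rose by 1.30 (SE 0.20).

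Stress and inflammatory genes rose as well. The integrated stress and unfolded protein response had 19 of 28 genes higher (21 higher and 1 lower adjusted over the list alone), among them ATF3 (3.84), SESN2 (2.53) and DDIT3 (2.19), with a median of 0.82 (limma camera adjusted p = 2.37e-05, adjusted p = 0.355 with an estimated correlation). Hypoxia and glycolysis genes rose in 20 of 29 cases and fell in 3, also when adjusted over the list alone, with the glucose transporter SLC2A3 at 3.56 and a median of 0.81 (0.000219, adjusted p = 0.355 with an estimated correlation) that was 0.43 after removal of GC content and length trends. NF-kB and cytokine genes rose in 12 of 19 cases (13 adjusted over the list alone), including IL6 (4.40), CXCL2 (3.19) and CXCL8 (1.87), with a median of 1.06 (0.000376, adjusted p = 0.355 with an estimated correlation). Metallothioneins rose in 6 of 8 cases, also when adjusted over the list alone, with MT1G at 3.67 and a median of 1.5 (limma camera adjusted p = 0.00421, adjusted p = 0.355 with an estimated correlation). Epithelial genes rose in 9 of 13 cases, also when adjusted over the list alone, with the keratin KRT19 at 1.84 and a median of 0.53 (0.019, adjusted p = 0.355 with an estimated correlation) that was 0.31 after removal of the trends, with an adjusted p of 0.0868. YAP and TEAD targets rose in 8 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone), with the matrix growth factor CCN2 at 2.45 and a median of 0.39 (limma camera adjusted p = 0.0294, adjusted p = 0.355 with an estimated correlation). In the blocked fit their adjusted p was 0.0688, with quantile scaling 0.359, and after removal of the trends 0.115 with a median of 0.15. Heat shock genes rose in 9 of 18 cases and fell in 1 (10 and 2 adjusted over the list alone), with the chaperone DNAJB1 at 1.36 and a median of 0.54 (limma camera adjusted p = 0.0365, adjusted p = 0.355 with an estimated correlation). Their adjusted p was 0.0733 in the blocked fit, 0.482 with quantile scaling and 0.0516 without DEX 1, and their median was 0.21 after removal of the trends. In the MYC network 4 of 11 genes rose (4 adjusted over the list alone), among them the MYC antagonists MNT (0.98) and MXD1 (0.87), with a median of 0.35 (limma camera adjusted p = 0.0476, adjusted p = 0.355 with an estimated correlation). Its adjusted p was 0.0551 in the blocked fit, 0.0644 with quantile scaling and 0.201 after removal of the trends, where the median was 0.17. It was also above the threshold without VEH 1 (0.0511), VEH 2 (0.0584), DEX 1 (0.0615), DEX 3 (0.053), KJ-PYR-9 3 (0.0707) or KJ-PYR-9+DEX 3 (0.0523).

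Mitosis genes missed the threshold (limma camera adjusted p = 0.058, 3 of 30 higher and 4 lower) but were called lower in the blocked fit (0.00485), and NRF2 targets (0.138, 10 of 25 higher and 2 lower) were called after removal of the trends (0.0143). With an estimated correlation the adjusted p was 0.751 for mitosis and 0.355 for NRF2 targets. No call was made for basal breast (0.141), E2F and DNA replication (0.173), MYC-dependent metabolism (0.413, 12 of 28 higher and 4 lower), ribosome biogenesis (0.421, 12 of 33 higher and 1 lower), p53 targets (0.421), cholesterol synthesis (0.685), SAGA and ATAC complexes (0.691) or aryl hydrocarbon receptor targets (0.978). The interferon list had 5 of 26 genes higher and 6 lower, with a median of -0.03, a mean of 0.07 and a test on the lower side (0.733).

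Among the largest falls were the chemokine CXCL5 (chromosome 4, 73995642 to 73998677), from 603 (SD 30.4) to 136 (SD 21.8), by 2.15 (SE 0.33, limma adjusted p = 0.00161), and the splicing factor SRSF1, from 814 (SD 106) to 195 (SD 56.2), by 2.09 (SE 0.34, 0.00206). IER3IP1, an endoplasmic reticulum protein, and TMED7, a cargo receptor of the secretory pathway, fell, with changes of -2.22 (SE 0.43, 0.00355) and -2.05 (SE 0.48, 0.00743), though TMED7 shares exons with a readthrough gene. ZNF483 and MZT1, a protein of the microtubule nucleating complex, fell, with changes of -2.08 (SE 0.34) and -1.96 (SE 0.35), as did NDUFC2, a subunit of respiratory complex I (-1.95, SE 0.35, 0.0027), which also shares exons with a readthrough gene. HMOX1 rose from 4059 (SD 388) to 8893 (SD 713), by 1.13 (SE 0.14, 0.000644). KAT2A rose from 474 (SD 20.7) to 616 (SD 11.4), by 0.38 (SE 0.11, limma adjusted p = 0.0163), but stood at -0.25 (0.272) after removal of GC content and length trends, and its adjusted p was 0.0541 without VEH 2 and 0.0583 without KJ-PYR-9 3.

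In all, limma called 5835 of 13616 genes, including 3455 upregulated and 2380 downregulated genes, and 1763 of them changed at least 2-fold. TMM rescaling gave 2970 higher and 3038 lower genes, quantile scaling 2832 and 3120, and edgeR 3406 and 3655. After removal of GC content and length trends 3081 genes were called, 1645 of them higher and 1436 lower, and 2101 of these were shared with the 5835. The blocked fit called 7897 genes, which shared 5825 with the 5835. The count was 3489 without VEH 1 and 3393 without KJ-PYR-9 3.

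The third comparison asked which genes changed within 3 h of MB-3. HMOX1 rose from 4780 (SD 284) to 13943 (SD 958), by 1.54 (SE 0.08, limma adjusted p = 0.00102). Further genes of the oxidative stress response rose, namely OSGIN1 (chromosome 16, 83953240 to 83966332), from 63.4 (SD 13.9) to 192 (SD 25.7), by 1.5965 (SE 0.16, 0.0466), and the thioredoxin reductase TXNRD1 (chromosome 12, 104215779 to 104350307), from 6678 (SD 229) to 10412 (SD 552), by 0.64 (SE 0.07, 0.0466). SOCS3, an inhibitor of cytokine signaling (chromosome 17, 78356778 to 78360925), fell from 310 (SD 37.1) to 128 (SD 21.4), by 1.28 (SE 0.14, 0.0466). CEBPD, a transcription factor of the inflammatory response, fell from 2366 (SD 67.3) to 1048 (SD 201), by 1.19 (SE 0.13, 0.0466), and DEPP1, a FOXO target, from 253 (SD 12.1) to 154 (SD 11.3), by 0.72 (SE 0.08, 0.0466). KAT2A, which encodes the enzyme that MB-3 inhibits, averaged 422 (SD 64.8) in MB3 and 483 (SD 59.2) in VEH2 (-0.20, SE 0.14, limma adjusted p = 0.527). MYC averaged 2244 (SD 265) and 2313 (SD 166), a difference of -0.05 (SE 0.11, 0.852) that turned to 0.007 after removal of GC content and length trends, 0.009 without VEH2 2 and 0.05 without MB3 1.

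These 6 genes, 3 higher and 3 lower, were all that limma called of 10048. At an unadjusted p under 0.05 there were 1377, and edgeR called 16 and DESeq2 154 (30 higher and 124 lower). The blocked fit called 14, of which 4 were among the 6, and gave TXNRD1 and DEPP1 an adjusted p of 0.0547 each, where quantile scaling gave 0.0529 and 0.0523. The GC and length removal gave 11 and the trended and robust variance 11, with DEPP1 at 0.0511. Without VEH2 1, 2 or 3 limma called 1, 1 and 2 genes, and without MB3 1, 2 or 3 it called 3, 1 and 2. In these reduced fits HMOX1 was called each time, OSGIN1 without VEH2 3, SOCS3 without MB3 1 and CEBPD without MB3 1 or MB3 3. The other calls were lost, with adjusted p of 0.0502 to 0.398. MB3 1 stood apart from MB3 2 and MB3 3, with a chi-square per degree of freedom of 14.98 and 19.09, against 3.42 between MB3 2 and MB3 3.

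**Figure D2:**
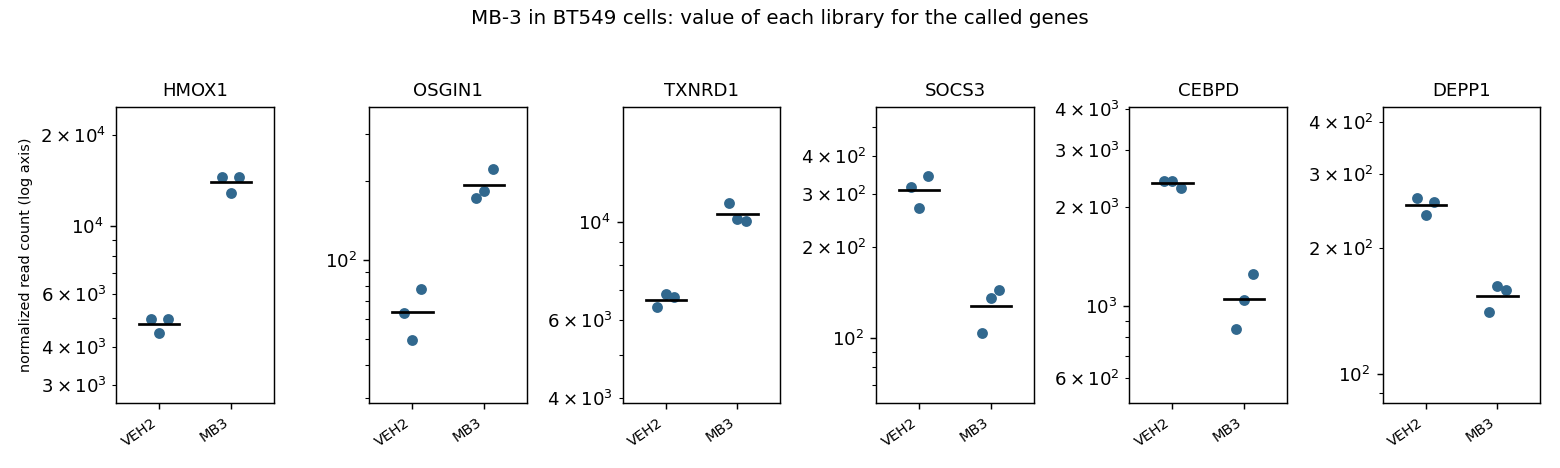
Normalized read counts (log axis) of the 6 called genes HMOX1, OSGIN1, TXNRD1, SOCS3, CEBPD and DEPP1 in VEH2 and MB3, with 1 point per library and a bar at the mean of 3. HMOX1 went from a mean of 4780 to 13943 and SOCS3 from 310 to 128.

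At the level of lists, NRF2 targets were called higher after MB-3, with 3 of 23 genes up (5 adjusted over the list alone) and a median of 0.11 (limma camera adjusted p = 0.00272, adjusted p = 0.353 with an estimated correlation). The glutathione synthesis gene GCLM stood at 0.65 (limma adjusted p = 0.161). The NF-kB list was called lower with a median of -0.25 (limma camera adjusted p = 0.00135, adjusted p = 0.476 with an estimated correlation), though none of its 15 genes passed over all genes (4 fell adjusted over the list alone). Stress response genes were called higher with a median of 0.14 (0.00384, adjusted p = 0.486 with an estimated correlation), with 0 of 27 passing over all genes and 2 higher and 1 lower adjusted over the list alone. DDIT3, a factor of that response, stood at 0.85. Glucocorticoid-responsive genes were called lower with a median of -0.22 (limma camera adjusted p = 0.00734, adjusted p = 0.476 with an estimated correlation), with 1 of 17 genes lower (1 higher and 4 lower adjusted over the list alone). YAP and TEAD targets were called lower with a median of -0.09 (0.0144, adjusted p = 0.567 with an estimated correlation), with 0 of 17 genes passing (5 lower adjusted over the list alone). The E2F list was called lower with a median of -0.06 (0.0497, adjusted p = 0.748 with an estimated correlation), with 0 of 30 genes passing either way, and its adjusted p was 0.0769 in the blocked fit and 0.0516 after removal of GC content and length trends. It was 0.252 without VEH2 1, 0.0616 without VEH2 2 and 0.379 without MB3 3, where that of the stress response was 0.0983. The removal of the trends left medians of -0.16 for NF-kB genes, -0.07 for glucocorticoid-responsive genes, -0.06 for YAP targets and -0.03 for the E2F list. The glucocorticoid median was -0.35 without VEH2 1 and -0.11 without MB3 1, the YAP median -0.14 without VEH2 3 and -0.26 without MB3 3, the NRF2 median 0.18 without MB3 3, and the E2F median -0.02 without VEH2 1 and -0.11 without VEH2 3.

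The other lists had no limma camera call in MB3. Ribosomal proteins, heat shock genes, aryl hydrocarbon receptor targets and metallothioneins each had an adjusted p of 0.0657. All 4 passed once GC content and length trends were removed, ribosomal proteins at 0.009, heat shock genes at 0.00223, aryl hydrocarbon receptor targets at 0.00809 and metallothioneins at 0.00741. With an estimated correlation they had 0.802, 0.567, 0.484 and 0.484 in the same order. Metallothioneins also passed in the blocked fit (0.0127). The interferon list had an adjusted p of 0.108, mesenchymal genes 0.304, mitosis 0.31, epithelial genes and p53 targets 0.434, the MYC network 0.474, hypoxia 0.476, MYC-dependent metabolism 0.513, immediate early genes 0.541, and SAGA and ATAC complexes and basal breast 0.908. For cholesterol synthesis it was 0.88, with a median of 0.02 and a test on the lower side, and for ribosome biogenesis 0.944, with a median of 0.01 and a mean of -0.03.

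DEX was compared with VEH in the same fit, with the groups as labelled. An exchange of the DEX and KJ-PYR-9+DEX labels is not excluded. DEX would then take the levels given below for KJ-PYR-9+DEX. There PDK4 was also high, MYC and FOS rose less over VEH, and IL6 lay below VEH. PDK4 (chromosome 7, 95583499 to 95596516) rose from 7.31 (SD 3.98) to 1328 (SD 419), by 7.41 (SE 0.37, limma adjusted p = 1.4e-06). TSC22D3, a leucine zipper protein that glucocorticoids induce, rose from 28.1 (SD 13.8) to 625 (SD 256), by 4.49 (SE 0.40), and SGK1 from 737 (SD 236) to 15164 (SD 2981), by 4.40 (SE 0.23). Of 26 glucocorticoid-responsive genes 21 rose and none fell (23 adjusted over the list alone), with a median of 1.89 (limma camera adjusted p = 3.19e-19, adjusted p = 0.0797 with an estimated correlation). MYC rose from 1806 (SD 598) to 18424 (SD 1364), by 3.40 (SE 0.21, 4.07e-06). Immediate early genes rose in 24 of 30 cases (25 higher and 1 lower adjusted over the list alone), among them NR4A2 (6.05, SE 0.39), FOS (5.87, SE 0.30) and NR4A1 (5.01, SE 0.31), with a median of 2.00 (limma camera adjusted p = 6.5e-19, adjusted p = 0.111 with an estimated correlation). All 8 metallothionein genes rose, also when adjusted over the list alone, with MT1G at 3.41 (SE 0.51), MT1X at 3.09 (SE 0.30) and MT1E at 2.64 (SE 0.42), and a median of 2.46 (limma camera adjusted p = 3.17e-07, adjusted p = 0.111 with an estimated correlation).

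NF-kB and cytokine genes rose in 9 of 19 cases with DEX, also when adjusted over the list alone, led by IL6 from 114 (SD 81.6) to 4268 (SD 810), by 5.46 (SE 0.46), with a median of 1.499 (limma camera adjusted p = 3.68e-05, adjusted p = 0.589 with an estimated correlation). This median was 0.94 after removal of GC content and length trends and 0.92 without VEH 2. Under an exchange of the DEX and KJ-PYR-9+DEX labels, the changes in this paragraph would belong to KJ-PYR-9+DEX, and IL6 in DEX would lie below its VEH level. The stress response had 11 of 28 genes higher (15 adjusted over the list alone), with ATF3 at 3.44, CEBPB at 2.51 and a median of 0.54 (limma camera adjusted p = 9.75e-05, adjusted p = 0.656 with an estimated correlation). The other 19 lists were not called, and the lowest of their adjusted p was 0.0847, for mesenchymal genes. With GC content and length trends removed 5 of them were called higher, mesenchymal genes (limma camera adjusted p = 5.37e-05), hypoxia genes (0.00175), heat shock genes (0.00744), YAP and TEAD targets (0.0113) and ribosomal proteins (0.0335). In the same order the adjusted p with an estimated correlation was 0.716, 0.948, 0.589, 0.716 and 0.948. The ubiquitin ligase TRIM17 fell from 89.0 (SD 4.37) to 16.5 (SD 10), by 2.56 (SE 0.40, 0.00238), and the prolyl hydroxylase EGLN2 from 282 (SD 35.7) to 76.8 (SD 34.8), by 1.97 (SE 0.29). SEMA4G, a semaphorin, fell by 1.94 (SE 0.26, 0.00104). The transcription factor ZIC4 (-1.66, SE 0.22, 0.000804) and MST1 (-1.72, SE 0.39, limma adjusted p = 0.0148, 0.0594 without VEH 3) fell as well.

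In all, limma called 2386 genes in DEX as labelled, including 1294 upregulated and 1092 downregulated genes. Under quantile scaling 1237 were higher and 1845 lower. The blocked fit called 5925 genes, which included all 2386. The removal of GC content and length trends gave 1258, DESeq2 gave 3737, and thinning every library to the reads of the shallowest gave 1191. The count was 1326, 1055 and 961 without VEH 1, 2 and 3, 865, 1187 and 3620 without DEX 1, 2 and 3, and 3940 without KJ-PYR-9+DEX 3.

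KJ-PYR-9+DEX was compared with DEX to give the effect of KJ-PYR-9 where DEX was present. An exchange of these labels is not excluded and would turn every direction in this comparison. Of the 30 immediate early genes, 22 would then be higher and 2 lower. MYC was lower in the libraries labelled KJ-PYR-9+DEX, at 4160 (SD 440) against 18424 (SD 1364), a fall of 2.15 (SE 0.21, limma adjusted p = 5.71e-05). CXCL8, a neutrophil chemokine, fell from 1646 (SD 177) to 33.5 (SD 13.5), by 5.64 (SE 0.38). IL6 fell from 4268 (SD 810) to 89.8 (SD 31.8), a change of -5.61 (SE 0.46), and CXCL2 from 4409 (SD 1090) to 146 (SD 35.9), a change of -4.91 (SE 0.35). NR4A2 (-5.13, SE 0.39), FOS (-4.74, SE 0.30) and NR4A1 (-4.41, SE 0.31) fell too. Of 30 immediate early genes 22 fell and 2 rose, also when adjusted over the list alone, with a median of -1.74 (limma camera adjusted p = 1.91e-06). Of 19 NF-kB and cytokine genes 11 fell, also when adjusted over the list alone, with a median of -1.21 (0.012). Histone genes rose in 16 of 29 cases and fell in 1, also when adjusted over the list alone, with a median of 0.53 (0.0136, 0.482 after removal of GC content and length trends). These 3 lists each had an adjusted p = 0.897 with an estimated correlation. Without DEX 3 the limma camera adjusted p was 0.0778 for NF-kB genes and 0.0926 for histones, and without KJ-PYR-9+DEX 2 it was 0.0725 for histones, whose median was 0.02 after removal of the trends.

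H4C2 (1.90, SE 0.32), H4C8 (1.597, SE 0.29) and H2AC13 (1.14, SE 0.27) were among the risen histone genes, and H2AC13 stood at 0.24 (limma adjusted p = 0.473) after removal of the trends. FAM43A rose from 441 (SD 40.8) to 3524 (SD 426), by 2.99 (SE 0.15), and TRIM17 from 16.5 (SD 10) to 153 (SD 34.4), by 3.32 (SE 0.40). The membrane transporter SLC4A11 rose by 2.76 (SE 0.25), the Wnt antagonist NKD2 by 2.65 (SE 0.28) and the dehydrogenase D2HGDH by 2.54 (SE 0.63, limma adjusted p = 0.00453, 0.0518 after removal of the trends). Mitosis genes (limma camera adjusted p = 0.132, 5 of 30 higher and 18 lower) were called lower in the blocked fit (0.00834), and stress response genes (0.147, 5 of 28 higher and 12 lower) after removal of the trends (0.000267), each with an adjusted p = 0.897 with an estimated correlation.

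In all, limma called 9351 of 13616 genes in this comparison, including 4569 upregulated and 4782 downregulated genes. After removal of GC content and length trends 4277 were called, 2245 of them higher and 2032 lower, of which 2794 kept their direction and 402 were called in the opposite direction. With trends removed and a block the count was 5682, and with a block alone 10257, which shared 9323 with the 9351.

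The interaction asked whether the effect of KJ-PYR-9 differed with DEX. MYC averaged 1806 in VEH, 18424 in DEX, 9853 in KJ-PYR-9 and 4160 in KJ-PYR-9+DEX, an interaction of -4.63 (SE 0.30, limma adjusted p = 4.38e-06). FOS averaged 108, 6008, 17528 and 231 in the same order (-12.13, SE 0.43), ATF3 332, 3597, 4804 and 171 (-8.23, SE 0.22), and IL6 114, 4268, 2035 and 89.8 (-10.01, SE 0.64). Interactions of NR4A2 (-10.90, SE 0.55), NR4A1 (-10.69, SE 0.44), EGR1 (-9.20, SE 0.48), CXCL2 (-8.10, SE 0.50) and CXCL8 (-7.51, SE 0.54) were also negative, as were those of DDIT3 (-4.40, SE 0.48) and SESN2 (-3.69, SE 0.47). HMOX1 averaged 4059, 3161, 8893 and 2966 (-1.21, SE 0.20). Positive interactions were led by TRIM17, at 89.0, 16.5, 34.1 and 153 (4.71, SE 0.56), with EGLN2 (3.28, SE 0.41), the smooth muscle myosin MYH11 (3.23, SE 0.29), SEMA4G (3.21, SE 0.37) and FAM43A (3.12, SE 0.21). With the DEX and KJ-PYR-9+DEX labels exchanged, the median of the immediate early genes was -1.373 in place of -4.578.

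**Figure D3:**
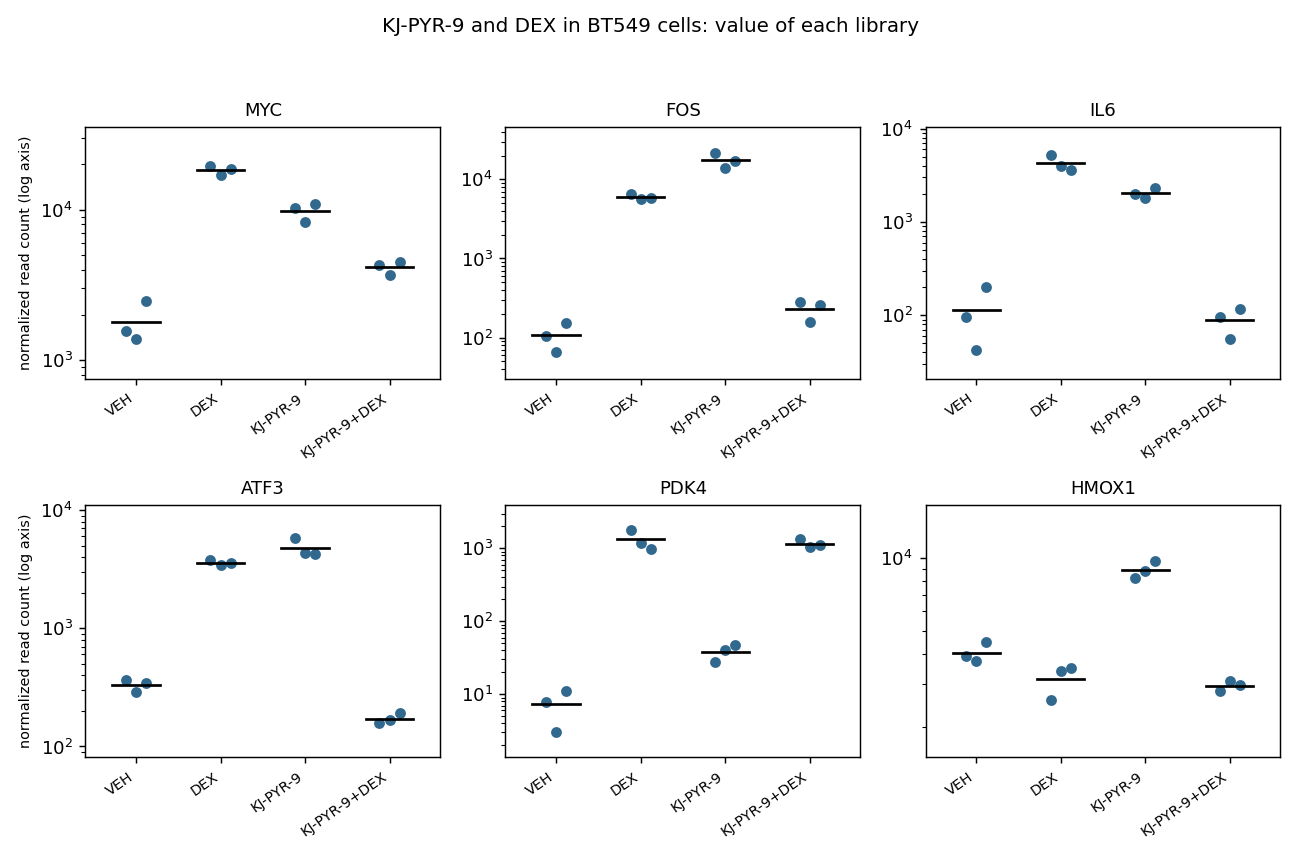
Normalized read counts (log axis) of MYC, FOS, IL6, ATF3, PDK4 and HMOX1 in VEH, DEX, KJ-PYR-9 and KJ-PYR-9+DEX, with 1 point per library and a bar at the mean of 3. FOS averaged 108, 6008, 17528 and 231 in these groups, and PDK4 7.31, 1328, 38.3 and 1164.

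Immediate early genes had lower interactions in 26 of 30 cases (27 adjusted over the list alone), with a median of -4.58 (limma camera adjusted p = 1.87e-31, adjusted p = 0.0564 with an estimated correlation). NF-kB and cytokine genes followed with 13 of 19 (15 adjusted over the list alone), a median of -2.27 and an adjusted p of 9.53e-10 (limma camera, adjusted p = 0.33 with an estimated correlation). The stress response had 15 of 28 lower (17 adjusted over the list alone), with a median of -1.09 (limma camera adjusted p = 1.07e-08, adjusted p = 0.338 with an estimated correlation). Metallothioneins had 4 of 8 lower (5 adjusted over the list alone), with a median of -1.31 (0.0018, adjusted p = 0.338 with an estimated correlation). Heat shock genes had 3 of 18 lower (3 adjusted over the list alone), with a median of -0.55 (0.00994, adjusted p = 0.33 with an estimated correlation, 0.156 with quantile scaling). Ribosomal proteins had 6 of 46 lower (0 adjusted over the list alone, median -0.45, 0.000282), histones 7 of 29 (7 adjusted over the list alone, median -0.45, 0.022) and hypoxia genes 6 of 29 (6 adjusted over the list alone, median -0.24, 0.0284). These 3 lists had an adjusted p = 0.742 with an estimated correlation, and 0.448, 0.137 and 0.286 with quantile scaling. After removal of GC content and length trends the median was -0.25 for ribosomal proteins and -0.33 for heat shock genes. For histones the limma camera adjusted p was 0.0684 without VEH 1, 0.135 without DEX 2, 0.0918 without KJ-PYR-9 2 and 0.097 without KJ-PYR-9+DEX 1, and the median was -0.26 without DEX 2, -0.22 without KJ-PYR-9 2 and -0.25 without KJ-PYR-9+DEX 3. For hypoxia genes it was 0.0736 without VEH 1, 0.0541 without VEH 2, 0.116 without DEX 3, 0.0557 without KJ-PYR-9 3, 0.114 without KJ-PYR-9+DEX 1 and 0.083 without KJ-PYR-9+DEX 2, and the median was -0.39 without VEH 3 and -0.37 without KJ-PYR-9+DEX 3.

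In all, limma gave an interaction in 2283 genes, 973 higher and 1310 lower. The shares turned with the scaling, with 58.5% higher under quantile scaling and 53.3% under TMM against 42.6% as deposited, and the median of all genes moved from -0.109 to 0.0348 under quantile scaling. The blocked fit gave 4399, and in it 2 further lists were called lower, the interferon list (limma camera adjusted p = 0.0392, 0.124 without the block) and mesenchymal genes (0.0476, 0.0563 without the block). With GC content and length trends removed mesenchymal genes (limma camera adjusted p = 0.000924) and the NRF2 list (0.0296, 0.0563 as deposited) were called lower. With an estimated correlation the interferon list had 0.844, mesenchymal genes 0.742 and the NRF2 list 0.338. With every library thinned to the reads of the shallowest there were 1284. The count was 1469 without KJ-PYR-9 1 and 1495 without KJ-PYR-9 2.

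The 3 treatments were set side by side. Over the 9858 genes tested in all, HMOX1 was the 1 gene called in the same direction in siMYC (0.80), KJ-PYR-9 (1.13) and MB3 (1.54), of 2 called in all 3. The other was DEPP1, which rose in siMYC (0.83) and fell in KJ-PYR-9 (-0.59) and MB3 (-0.72). Of the 13137 genes tested with both KJ-PYR-9 and siMYC, those called higher in both numbered 561, against 386 if independent, and those called lower in both 201 against 113, while opposite calls numbered 106 against 162 and 97 against 269. With MB3 (9976 genes tested in both), KJ-PYR-9 shared 2 genes called higher in both (0.862 if independent), HMOX1 and OSGIN1, which rose by 1.85 with KJ-PYR-9. SOCS3 and CEBPD were the 2 called higher in KJ-PYR-9 (1.38 and 1.46) and lower in MB3 (0.862 if independent), and DEPP1 was the 1 called lower in both (0.564 if independent). SiMYC shared with MB3 (9860 genes tested in both) the rises of HMOX1 and TXNRD1 (0.57 in siMYC), the 2 called higher in both (0.316 if independent). With so few genes called in MB3, these counts say little about sharing. Between KJ-PYR-9 against VEH and KJ-PYR-9+DEX against DEX, with 13616 genes tested, 2510 were higher in both (1159 if independent) and 1808 lower in both (836 if independent), while opposite calls numbered 249 against 1213 and 152 against 799. An exchange of the DEX and KJ-PYR-9+DEX labels, which is not excluded, would swap the agreeing and opposite counts of this pair. The counts of this paragraph were not taken again after removal of GC content and length trends.

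Fold changes were correlated across genes, which are not independent replicates, in 4 pairs of comparisons. None reached an adjusted exact permutation p under 0.24. Every other split keeps part of the real difference between the groups, and the splits do not keep replicate numbers together. The test therefore had little power, and its p does not decide whether the treatments moved the same genes. In each pair other splits also gave an r of larger size than the real grouping. The largest were 0.556, 0.525, 0.383 and 0.619, in the order in which the pairs follow. KJ-PYR-9 and siMYC gave r = 0.328 and rho = 0.387 over 13137 genes (exact permutation p = 0.22), and r = 0.144 after removal of GC content and length trends. KJ-PYR-9 and MB3 gave r = -0.454 and rho = -0.533 over 9976 genes (exact permutation p = 0.12), with r = -0.0746 after that removal, -0.255 without MB3 1 and -0.511 without MB3 3, where the exact permutation p was 0.01. SiMYC and MB3 gave r = -0.227 and rho = -0.261 over 9860 genes (exact permutation p = 0.24), with -0.0322 after the removal and -0.113 without MB3 1. KJ-PYR-9 without and with DEX gave r = 0.489 and rho = 0.629 over 13616 genes (exact permutation p = 0.2), and r = -0.0291 after the removal.

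Sets of called genes were also carried from 1 comparison to another and tested with limma camera, 8 tests in all. Genes that fell with KJ-PYR-9 were lower in siMYC (adjusted p = 6.95e-07), and those that rose with KJ-PYR-9 were higher (0.0332). Genes that rose with siMYC were higher in KJ-PYR-9 (limma camera adjusted p = 0.00426, 0.0507 with at most 100 genes), with 90 of 265 called higher and 18 lower. Genes that fell with siMYC were lower in KJ-PYR-9 (0.0047, 0.0715 with at most 100 genes), with 82 of 269 called lower and 48 higher. In MB3, genes that rose with KJ-PYR-9 were lower (3.56e-06), genes that fell with KJ-PYR-9 were higher (0.000623), and genes that rose with siMYC were lower (limma camera adjusted p = 0.000999), while genes that fell with siMYC had no call (0.324). The called sets had an adjusted p = 0.491 with an estimated correlation, except the siMYC rises in MB3, which had 0.438. The sets were not tested again after removal of GC content and length trends. The Pearson correlation of fold change with GC content across genes was 0.326 in siMYC, 0.655 in KJ-PYR-9 and -0.586 in MB3. The directions of these sets therefore cannot be told apart from such trends.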

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

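The test of an exchange between the VEH and KJ-PYR-9 labels and the test of a lower MYC level alone were chosen after the result was seen. A first version of the thinning test scaled all libraries to equal totals and was replaced by 1 with the deposited scaling, with the same outcome.

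A difference between groups drew attention to 2283 genes whose KJ-PYR-9 effect in the presence of DEX differed from that in its absence. Of 100 draws of the 12 libraries into the 4 groups, 2 gave as many genes, the real grouping included, and the highest other draw gave 4064. These draws also break up the effects of DEX and KJ-PYR-9 alone, so they test the grouping as a whole and not the interaction alone. In 99 other draws within replicate numbers, 3 gave as many. Those with 9057, the highest, and 8180 genes set all libraries with KJ-PYR-9 against all without it, so they count a difference that goes with KJ-PYR-9 and not an interaction. For the other comparisons 3 libraries against 3 make 10 splits, too few for a share under 0.05, and the real split was 1 of 10 as large in each. The real and highest other counts were 2386 and 0 for siMYC, 5835 and 0 for KJ-PYR-9, 6 and 0 for MB3, 2386 and 0 for DEX, and 9351 and 1 for KJ-PYR-9+DEX. Each other split mixes libraries of both groups, so counts near 0 follow from any large difference between the groups, whatever its source.

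The interaction medians of whole lists were also picked out by this difference between groups. They were -0.45 for cytosolic ribosomal proteins, -0.45 for replication-dependent histones, -1.09 for the integrated stress and unfolded protein response, -0.55 for the heat shock response and -1.31 for metallothioneins. Immediate early genes gave -4.578, NF-kB genes -2.27 and hypoxia genes -0.24. Single genes picked out in the same way were MYC at -4.63, FOS at -12.13, NR4A2 at -10.90, NR4A1 at -10.69, IL6 at -10.01, EGR1 at -9.20, ATF3 at -8.23, CXCL2 at -8.10, CXCL8 at -7.51, DDIT3 at -4.40 and SESN2 at -3.69. On the higher side these were TRIM17 at 4.71, EGLN2 at 3.28, MYH11 at 3.23, SEMA4G at 3.21 and FAM43A at 3.12.

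Immediate early genes and MYC were higher with DEX or KJ-PYR-9 alone than with both, and MYC averaged 4160 with both against 1806 in VEH. An exchange of the VEH and KJ-PYR-9 labels is argued against by the immediate early genes alone, where the libraries labelled KJ-PYR-9 lay 16.92 percentile points farther from the VEH2 libraries than those labelled VEH. The libraries ranged from 52.7 to 67.8 in VEH, 94 to 95.4 in KJ-PYR-9 and 66.3 to 71.6 in VEH2. But VEH2 comes from another experiment, and in the interferon list KJ-PYR-9 (82.3) lay nearer to VEH2 (17.7) than VEH (92.6) did. GC content and transcript length are argued against as the whole source, since their removal left the median interaction at -4.571. An exchange of the DEX and KJ-PYR-9+DEX labels was to be ruled out if it left more genes with an interaction than the 2296 of the labelled groups after removal of these trends, and it left 4613 (9759 against 2283 on the deposited values). After the values were seen that bound was judged wrong, because an exchange sets no limit on genes outside the pattern. The exchange took the median of the immediate early genes from -4.571 to -0.4664 (-1.373 on the deposited values). It took MYC from -4.733 to 0.4098 (-0.3359 on the deposited values). Such a shrinkage follows for any gene whose 2 KJ-PYR-9 effects have opposite signs, so it does not speak for an exchange. With the exchange, 9 of 30 immediate early genes were still called lower and 2 higher with trends removed, and 18 and 3 on the deposited values. As labelled, the 2 KJ-PYR-9 effects shared their sign in 78.2% of genes (r = 0.489), which an exchange would turn (with 249 and 152 genes higher and lower in both in place of 2510 and 1808), but r was -0.0291 with trends removed and no other sample checks these labels, so such an exchange cannot be told apart from an interplay of the 2 compounds, the biological explanation that the design names.

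Interferon genes were higher in siMYC libraries than in siCtl libraries. Leukocytes in the siMYC libraries are argued against as the source of most of this, since 7 leukocyte markers summed to 1.025 times their siCtl level while the interferon genes summed to 16.6 times theirs, and PTPRC, which all leukocytes carry, averaged 22.95 (SD 9.03) in siMYC and 27.63 (SD 10.1) in siCtl. The sum was led by CORO1A, whose high baseline would hide a small share, and the 6 other markers summed to 1.402 times their siCtl level, with CD68 at 3.208 times. A lower MYC level alone is the biological explanation that the design names, and in KJ-PYR-9 against VEH the median of the interferon list was -0.02991. That value does not decide, because KJ-PYR-9 was given for hours and the siRNA for days and MYC mRNA was higher with KJ-PYR-9. The interferon list also stood high in VEH already. Its median within-library percentile averaged 92.6 in VEH, which received no siRNA, 26.6 in siCtl and 95.5 in siMYC. A lower MYC level cannot be told apart from other effects of the siRNA pool, or from whatever set the list high in VEH, which was not tested.

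Many genes were called in KJ-PYR-9 against VEH, and fold changes ran with GC content. Unequal depth is argued against for this comparison, since 4550 genes were called after every library was thinned to the reads of the shallowest, while the same thinning took DEX from 2386 to 1191 and the interaction from 2283 to 1284. GC content and transcript length trends cannot be told apart from an effect of KJ-PYR-9 for a large part of the called genes. After their removal 3081 genes were called, between the 2 bounds set in advance, and 4670 in the paired fit. Of the 3081 genes, 2101 were among the 5835 called before the removal, so most of the 5835 calls were not kept in that fit. An effect of KJ-PYR-9 itself stays among the open explanations.

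A signal in features without a gene symbol was above the highest VEH library, at 1.861% of the reads, in 7 libraries. The shares were 26.04% in DEX 1, 2.071% in DEX 3, 3.098% in KJ-PYR-9 1, 5.445% in KJ-PYR-9 3, 4.826% in KJ-PYR-9+DEX 1, 2.424% in KJ-PYR-9+DEX 2 and 8.722% in KJ-PYR-9+DEX 3. In DEX 1 the largest such feature held 12.1% of the reads.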

How the results depend on the processing

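The alternatives with GC content and length trends removed, the edgeR, pseudocount, scaling and trended variance fits for MB3, the fits without DEX 1 and KJ-PYR-9+DEX 3, the thinned fits, the lists with 1 library left out and the reduced correlations were chosen after the data were seen. Of 112 named gene results, pseudocounts of 0.5 and 4 kept the call and direction of 112, TMM and edgeR 111, trended variance and DESeq2 110, quantile scaling 109, the removal of trends 104 and the replicate block 94. Leaving out each library in turn kept 1025 of 1128 checks, lost 101 and reversed 2. Of 53 called lists, 48 kept the call with a block, 45 with trends removed, 42 with quantile scaling, 39 with fry and 0 with an estimated correlation, and leaving out each library in turn kept 459 of 492 list checks and lost 33. MB-3 genes with a low level were absent from the data, and in the knockdown and inhibitor designs 1.5-fold changes were mostly missed on simulated data. For MB3 the simulated genes all had the same dispersion. Small changes are therefore not bounded in any of the experiments. The cause was not tested for the values that follow.

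In siMYC the block gave 470 genes, DESeq2 3782 and leaving out 1 library 432 to 3983, and the block, whose pairs did not correlate, ended 16 of the named calls. For KJ-PYR-9 the removal of trends gave 3081, and leaving out 1 library 3393 to 6838. For MB3 trended variance gave 11, the block 14, edgeR 16, edgeR with RLE factors 16, voom 20, DESeq2 154, the removal of trends 11, the same with a block 3, and leaving out 1 library 1 to 3. For DEX the block gave 5925, DESeq2 3737, the removal of trends 1258, thinning to the shallowest library 1191, and leaving out 1 library 865 to 3940. For KJ-PYR-9+DEX against DEX the removal of trends gave 4277 and, with a block, 5682. For the interaction the block gave 4399, thinning 1284, and leaving out 1 library 1469 to 2731.

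With an estimated correlation 0 lists were called in each of the 6 comparisons. Fry called 1 list in MB3, 11 in DEX, 5 in KJ-PYR-9+DEX against DEX and 15 in the interaction. The removal of trends gave 10 lists in DEX, and quantile scaling gave 5 in KJ-PYR-9+DEX against DEX and 4 in the interaction. Without DEX 1 and KJ-PYR-9+DEX 3 the counts were 7365 for KJ-PYR-9, 1764 for DEX and 1827 for the interaction. The correlation of KJ-PYR-9 and siMYC ranged from 0.259 to 0.381 when 1 library was left out, that of KJ-PYR-9 and MB3 from -0.511 to -0.255, that of siMYC and MB3 from -0.272 to -0.113, and that of KJ-PYR-9 without and with DEX from 0.406 to 0.517. The last turned to -0.0291 with trends removed. The called transferred sets had adjusted p of 0.491 and 0.438 with an estimated correlation, and those from siMYC 0.0507 and 0.0715 in KJ-PYR-9 with at most 100 genes. KAT2A turned to -0.25 in KJ-PYR-9 with trends removed, with and without a block. MYC in MB3 turned to 0.007175 with trends removed, with and without a block, and ranged from -0.108 to 0.05316 when 1 library was left out, with 0.008724 without VEH2 2. For the inhibitor experiment the block kept the calls of all named genes, and the lists whose call it changed are given in the report.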

Other observations

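No explanation was tested in this part, and its genes and lists were chosen after their values were seen. Glucocorticoid-responsive genes differed in how they stood in the presence of both compounds. Of 26 tested in KJ-PYR-9+DEX against DEX, 11 were higher, 4 lower and 11 not called (10 higher and 4 lower adjusted over the list alone), and the list was not called (limma camera adjusted p = 0.328). Over all 13616 genes 4569 were higher and 4782 lower, 68.7% in all, so calls in both directions were not particular to this list. An exchange of the DEX and KJ-PYR-9+DEX labels, which is not excluded, would turn each direction of this comparison here, to 4 higher and 11 lower, with FKBP5, ZBTB16 and PER1 lower and SGK1 and DUSP1 higher. PDK4, the kinase that restrains pyruvate dehydrogenase, averaged 7.31 in VEH, 1328 in DEX, 38.3 in KJ-PYR-9 and 1164 in KJ-PYR-9+DEX (n = 3 each), and KJ-PYR-9+DEX against DEX gave -0.15 (SE 0.37, limma adjusted p = 0.719). The level of KLF9, a transcription factor that glucocorticoids induce, was 206 in VEH, 1998 in DEX, 399 in KJ-PYR-9 and 1884 in KJ-PYR-9+DEX, where the same comparison gave -0.07 (SE 0.17, limma adjusted p = 0.718). Higher levels in KJ-PYR-9+DEX than in DEX were called for FKBP5, a co-chaperone of the glucocorticoid receptor, for ZBTB16, a zinc finger repressor, and for PER1, a clock gene. FKBP5 averaged 9.50, 41.6, 6.62 and 159 in VEH, DEX, KJ-PYR-9 and KJ-PYR-9+DEX, a rise of 1.92 (SE 0.35, limma adjusted p = 0.000742) between the DEX groups. ZBTB16 averaged 0.773, 21.8, 1.36 and 162, a rise of 2.86 (SE 0.32, limma adjusted p = 9.88e-05). PER1 averaged 351, 1179, 1240 and 2081, a rise of 0.82 (SE 0.17, limma adjusted p = 0.00155). Lower levels in KJ-PYR-9+DEX than in DEX were called for SGK1, a kinase of ion transport, which fell by 2.96 (SE 0.23, limma adjusted p = 1.84e-05), and for DUSP1, a phosphatase of MAP kinases, which fell by 1.40 (SE 0.26, limma adjusted p = 0.000783).

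The level of the type I interferon list in vehicle or control libraries differed between the experiments. Over the 9858 genes tested in all 3 experiments, the median within-library percentile of its 17 shared members averaged 92.6 (SD 3.28) in VEH, 17.7 (SD 4.63) in VEH2 and 26.6 (SD 13.4) in siCtl, with 3 libraries each. It averaged 95.5 (SD 3.13) in siMYC. The means in DEX, KJ-PYR-9, KJ-PYR-9+DEX and MB3 were 92.7, 82.3, 80.6 and 20. Glucocorticoid-responsive genes stood at 61.7 in VEH, 59.0 in VEH2 and 55.9 in siCtl, and at 84.0 in DEX, 78.0 in KJ-PYR-9 and 86.8 in KJ-PYR-9+DEX. The 3 tables were normalized separately, the experiments were not compared by a test, and the percentiles describe these libraries.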
